A study of Mus musculus with 4 samples.

How the data were processed

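Liver RNA of male mice was measured on 4 Affymetrix 3' expression arrays, 1 for each of the groups wild type on chow, LASS2-/- on chow, wild type on high-fat diet and LASS2-/- on high-fat diet. Per the labels' protocols, total RNA was extracted with TRIZOL, checked for integrity, purified on RNeasy columns with DNase and labelled with the GeneChip 3' IVT Express kit. Per the labels, the diets held 10% and 60% of calories from fat and began at 3 weeks of age. The labels do not say whether an array held RNA of 1 mouse or of a pool. The labels carry no replicate numbers and no batch.

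The deposited values are log2 signals, 1 per probe set and array. Per the submitters' processing notes they were made with MAS5, the Affymetrix signal algorithm. Its version, the scaling target and any further step are not given in the sources used here, and no detection calls were used here. After conversion to the linear scale, the mean over the middle of the distribution, with 2% of probe sets trimmed from each tail, was 495.8 for wild type on chow, 495.8 for LASS2-/- on chow, 495.9 for wild type on high-fat diet and 496.0 for LASS2-/- on high-fat diet. The authors' scaling had therefore given every array nearly the same trimmed mean, and no further scaling was applied. Exact zeros, which are signals of 1 on the linear scale, numbered 280, 196, 299 and 342 on these arrays in the same order.

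The table held 45037 probe sets. Names came from the platform's gene numbers joined to a table of mouse genes on assembly GRCm38.p6. Of all probe sets, 34945 had a single gene symbol, 932 had several symbols and 9160 were not named here. The named probe sets covered 18193 symbols. A probe set was kept when it reached the array median on at least 1 of the 4 arrays. A gene was then represented by its kept probe set with the highest mean log2 signal, which left 12493 genes. For ratios, each array was floored at its own median log2 signal (6.17, 6.28, 6.19 and 6.19), and a ratio with the lower array under this floor is given as a bound. A gene under the floor on both chow arrays received a genotype ratio of 0.10 from the floors alone. The number of arrays limits the precision of every value.

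The 4 ratios were LASS2-/- over wild type on each diet and high-fat diet over chow in each genotype. Each received a count of genes at least 2-fold apart and no p-value, since each rests on 1 array per group. The genotype ratios of the diets share no array, nor do the diet ratios of the genotypes, so genes at least 2-fold apart in the same direction on both were counted, beside the count that independent lists of those sizes would give. Mean effects were tested with limma 3.58.1 in R 4.3.3 by an additive model of diet and genotype on log2 values without the floor. This fit has 4 arrays, 3 coefficients and 1 residual degree of freedom per gene, and the difference of the genotype effect between diets serves as its error. Empirical Bayes moderation used a trend in signal, and Benjamini-Hochberg adjusted p below 0.05 over all genes counted as passing. The variance drawn from genes of like signal weighed as 12.7 degrees of freedom, against 1 from the gene itself. Standard errors given after ± are these moderated ones and do not measure the spread of the single gene between arrays. The residual standard deviation was 0.800, 0.274, 0.184 and 0.128 log2 in 4 groups of genes of equal size, from the dimmest to the brightest. Computations also used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

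The comparisons, the tests, the alternatives, 36 gene lists and the rule for naming genes were set before the data were examined. The rule named the targeted gene, up to 12 genes per direction among those at least 2-fold apart in the same direction on both independent ratios, ranked by the smaller of the ratios, and 8 per direction for the difference of genotype ratios between diets. Symbols that are only clone or predicted-gene names were left out. Up to 4 members were named per list. Members named for having passed the limma test beyond these, and the other genes named from the limma results, were chosen after their values were seen. The lists hold 719 genes, of which 582 entered and 1 was not matched to the gene table. Each list's median log2 ratio was placed among 10000 random lists of the same size matched on signal in 20 bins, and a list was described with a comparison when its percentile was below 2.5 or above 97.5 on both independent ratios. These percentiles describe the list among genes of these arrays and carry no replicate error. Members passing limma were counted over all genes and again adjusted over the list alone.

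The alternatives were quantile normalization, scaling of the arrays to equal medians, a floor at the 25th percentile, a 1.5-fold threshold, the mean of all probe sets of a gene, leaving out probe sets ending in _x_at or _s_at, floored values in limma, no filter on signal and no trend in the moderation. The floor at the 25th percentile was also the limit for entering, so 16898 genes entered with it. A robust moderation with trend was added after the data were seen. Probe sets with several symbols or no name were left out of the gene counts and are described only as a count.

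The procedure was tested on simulated data built for the genotype effect, with 12493 genes, 200 changed genes and 20 simulations. Limma with trend found 60% of genes changed 2-fold and 79.8% of genes changed 4-fold, and 99.96% of the found genes had the right direction. Of the called genes, 12.7% were unchanged, above the nominal rate. Without trend it called 0 genes. The shared 2-fold rule found 20.1% of genes changed 2-fold and 79.2% of genes changed 4-fold, and a mean of 12.6 unchanged genes per simulation passed it. The lists were tested in 40 separate simulations of the chow genotype ratio, each with a list of 20 genes. Of lists shifted by 0.5 log2, 97.5% lay above the upper limit, and 10% of unchanged lists lay beyond either limit. The noise was independent between genes and fewer random lists were drawn than for the data. The 10% is therefore not the rate for lists whose genes move together.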

Results

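Transcript levels were measured in liver of male mice that were wild type or LASS2-/- and were fed chow or a high-fat diet, with 1 array in each of the 4 groups. Lass2 is the former name of Cers2, the ceramide synthase that makes very-long-chain ceramides. There were no replicates, so no value has an error between animals. The labels set out the groups, and the comparisons ask which genes differed with the genotype label on each diet and with the diet in each genotype. Of 18193 named genes, 12493 entered.

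Cers2, the targeted gene, had a log2 signal of 12.46 on the array labelled wild type chow, 12.32 on the array labelled LASS2-/- chow, 12.25 on the array labelled wild type high-fat diet and 12.32 on the array labelled LASS2-/- high-fat diet. Its log2 genotype ratio was -0.15 on chow and 0.07 on high-fat diet, and its probe set was brighter than 96.2% of all probe sets. It was therefore not lower on both arrays labelled LASS2-/-, and which part of the transcript the probe set reads was not determined. Among the 4 measured ceramide synthases, 0 passed limma for genotype over all genes and 0 adjusted over the list alone, and 0 had an unadjusted p under 0.05. Cers4 had a log2 genotype ratio of at most -0.50 on chow and -0.77 on high-fat diet. Cers5 had 0.07 and 0.46, and Cers6 had -0.12 and -0.31. Of 29 measured genes of sphingolipid synthesis and turnover, 0 passed for genotype on either count and 4 had an unadjusted p under 0.05, with list medians of 0.05 on chow and 0.00 on high-fat diet, and the chow median was -0.06 with arrays scaled to equal medians. The Y-linked Eif2s3y was bright on all 4 arrays, from 11.48 to 11.69, and Alb, which encodes albumin, ranged from 15.02 to 15.27.

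**Figure D1:**
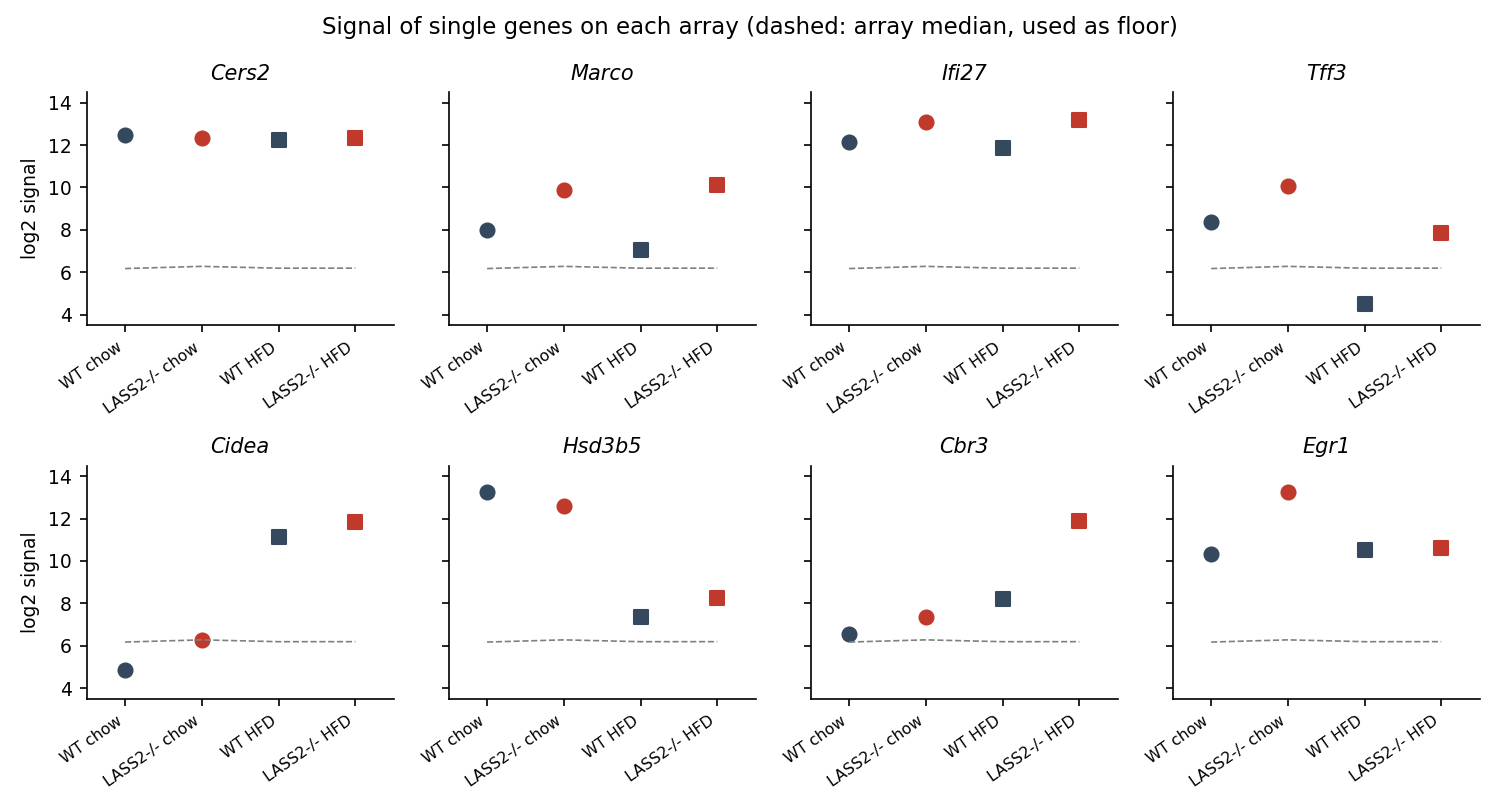
Log2 signal (vertical axis) of 8 genes on each of the 4 arrays (horizontal axis), with LASS2-/- arrays in red, high-fat arrays as squares and the array medians as a dashed line. Cers2 lay between 12.25 and 12.46 on all 4 arrays, while Marco was higher on both LASS2-/- arrays and Cidea on both high-fat arrays.

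The arrays of a shared diet were closer to each other than the arrays of a shared genotype. In the genes above the median signal, the standard deviation of the log2 difference was 0.257 between the chow arrays and 0.266 between the high-fat arrays, against 0.407 between the wild type arrays and 0.433 between the LASS2-/- arrays. Across all genes, the genotype ratios on chow and on high-fat diet had a Pearson r of 0.156 and a Spearman rho of 0.155. The diet ratios in wild type and in LASS2-/- had 0.533 and 0.444. With the floor at the 25th percentile, which also admitted dimmer genes (16898 in all), Pearson r was 0.036 for genotype and 0.25 for diet. Genes are not independent replicates, so no p-value accompanies these correlations.

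Marco, a scavenger receptor of macrophages, was 3.67-fold higher on the LASS2-/- than on the wild type array on chow and 8.44-fold higher on high-fat diet. Ccl5, a chemokine for T cells and monocytes, was 2.64-fold and 2.72-fold higher, and Lpl, which encodes lipoprotein lipase, was 2.18-fold and 2.37-fold higher. Tff3, a trefoil factor of mucosal epithelia, was 3.25-fold higher on chow and at least 3.18-fold higher on high-fat diet. Sult1e1, the estrogen sulfotransferase, was at least 3.23-fold and 5.57-fold higher, and Ubd, a ubiquitin-like modifier induced by inflammatory cytokines, was at least 2.34-fold and 9.59-fold higher. Robo1, a Slit receptor, was 2.76-fold and 2.23-fold higher.

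These genes came from 14 genes at least 2-fold higher and 2 at least 2-fold lower on both diets, where independent lists would share 2.14 and 0.26. Another 6 genes were 2-fold apart in opposite directions, where 1.49 would be. With the floor at the 25th percentile, among 16898 genes, 131 were shared higher and 67 lower. These were fewer together than the 205 then in opposite directions. The single-diet counts were 145 higher and 53 lower on chow and 184 higher and 61 lower on high-fat diet. With the floor at the 25th percentile the high-fat counts were 790 and 786. There the excess of higher genes on high-fat diet did not hold, but the floor and the genes entering changed together. Of the 12 named higher genes, 9 passed limma for the mean genotype effect. They had been chosen on the same ratios that this test uses, so passing is no separate support. Changes are given in log2 with a moderated standard error, which rests mostly on genes of like signal. It can be smaller than the spread of the single gene: Marco had ratios of 1.87 and 3.08 log2 and an error of 0.24. Marco changed by 2.48 ± 0.24 (adjusted p = 0.000391), Lpl by 1.19 ± 0.13 (adjusted p = 0.000774), Ccl5 by 1.42 ± 0.19 (adjusted p = 0.00267) and Robo1 by 1.31 ± 0.19 (adjusted p = 0.00358), each higher on both diets. Sult1e1 passed with adjusted p = 0.00267, Tff3 and Ubd each with 0.0026, Lce1h, at least 2.14-fold and 5.39-fold higher, with 0.0135 and Tinag, at least 2.15-fold and at least 2.92-fold higher, with 0.0474. Lce1h and Tinag did not pass with quantile normalization or with equal medians, and Tinag, Tff3 and Ubd did not pass with robust moderation. Wfdc15b, 2.08-fold and 2.84-fold higher, Ccr2, a monocyte chemokine receptor 2.08-fold and 2.20-fold higher, and Pvt1, at least 2.21-fold and at least 2.25-fold higher, did not pass. Neither lower gene passed: Shf was at least 2.09-fold and 2.31-fold lower and Tex12 at least 2.06-fold and at least 3.31-fold lower. In Pvt1, 3 of 4 probe sets, and in Ccr2, 2 of 3, had a mean genotype ratio over the diets in the same direction. With the mean of all probe sets the mean log2 genotype ratio was 0.34 for Pvt1 and 0.46 for Ccr2, against 1.16 and 1.10. With arrays scaled to equal medians, the chow counts were 104 higher and 95 lower and the shared counts 9 and 3, as every chow genotype ratio moved from a median over all genes of 0.03 to -0.07. In data simulated for this comparison, 12.6 unchanged genes were 2-fold apart in the same direction and as many in opposite directions, where the data had 14 and 2 in the same and 6 in opposite directions. The simulation thus had more genes in opposite directions than the data. Its noise may differ from that of the arrays, so it does not set how many shared genes noise alone would give.

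**Figure D2:**
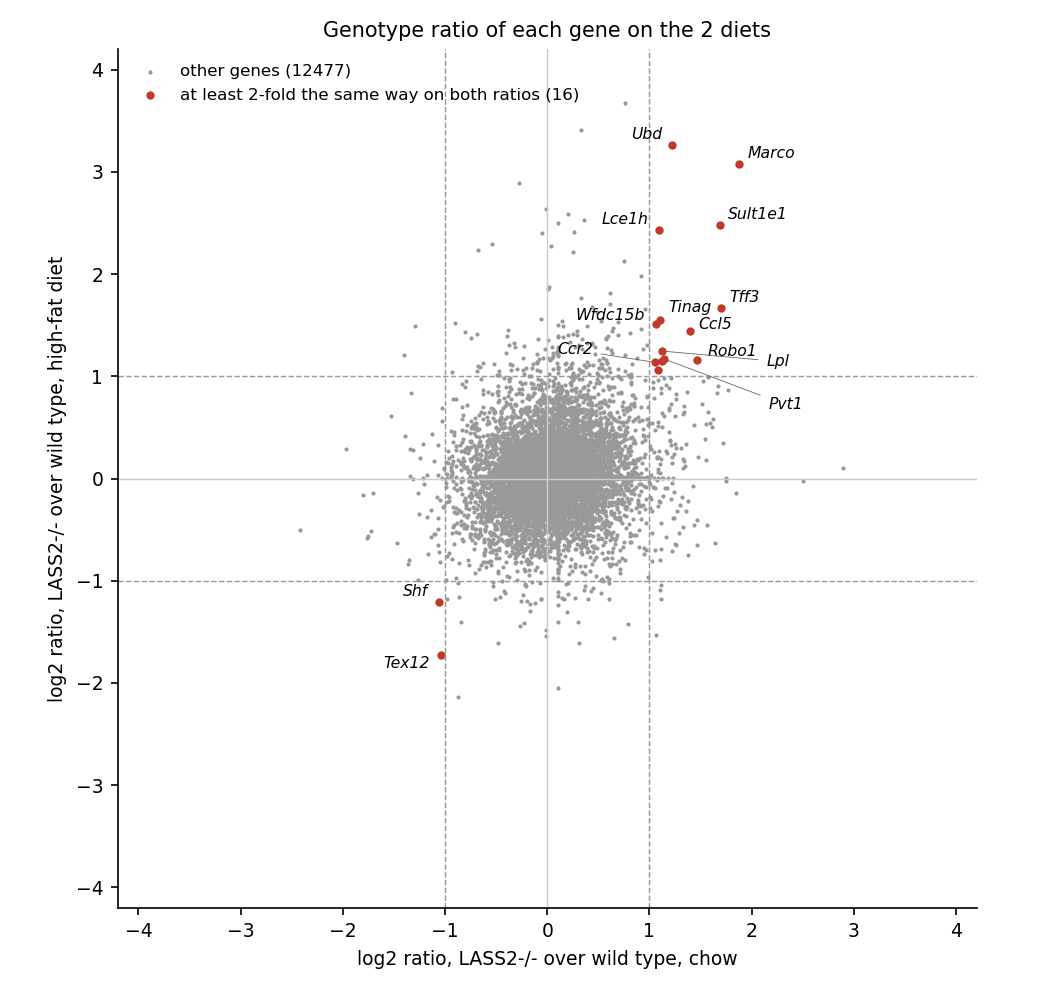
Log2 ratio of LASS2-/- over wild type on chow (horizontal axis) and on high-fat diet (vertical axis) for 12493 genes, 1 point per gene, with values floored at the array median and dashed lines at 2-fold. The 14 higher and 2 lower genes that were 2-fold apart on both diets are in red.

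Over both diets, 70 genes rose and 44 fell with the LASS2-/- label in limma. Among those that fell were Cyp2c37 by -1.13 ± 0.11 (adjusted p = 0.000434) and Cyp2c29 by -0.50 ± 0.07 (adjusted p = 0.00458), both cytochromes P450, Slco1a4, an organic anion transporter, by -1.50 ± 0.20 (adjusted p = 0.00267), and Ppp1r3c, a glycogen-targeting phosphatase subunit, by -1.01 ± 0.11 (adjusted p = 0.000998). Srebf1, a transcription factor of lipid synthesis, fell by 1.16 ± 0.18 (adjusted p = 0.00743) and Acaca, acetyl-CoA carboxylase, by 0.62 ± 0.12 (adjusted p = 0.0299). Pdk4, a pyruvate dehydrogenase kinase, rose by 1.25 ± 0.17 (adjusted p = 0.00267), Ccnd1, cyclin D1, by 0.98 ± 0.14 (adjusted p = 0.00397), and Saa2, a serum amyloid A gene, by 1.11 ± 0.15 (adjusted p = 0.0027). Because the difference between diets is the error of this test, it selects for genes that go the same way on both diets. The count depended on the settings: limma called 14 and 9 with quantile normalization, 11 and 11 with arrays scaled to equal medians, and 0 without trend, where 820 genes had an unadjusted p under 0.05 against 1294 with it. Of the 114 genes, 16 passed with every alternative other than the fit without trend, among them Marco, Lpl, Ccl5, Cxcl9, Ifi27, Sult1e1, Robo1, Cyp2c37, Ppp1r3c, Hamp2 and Leap2. Slco1a4, Srebf1, Acaca, Pdk4, Ccnd1 and Saa2 did not pass with quantile normalization, and Cyp2c29 did not pass with no filter. Srebf1, Acaca, Ccnd1 and Saa2 did not pass with equal medians either. With robust moderation limma gave adjusted p = 0.667 for Slco1a4, 0.757 for Srebf1 and 0.346 for Saa2, and Pdk4 and Ccnd1 did not pass. With the mean of all probe sets Acaca had adjusted p = 0.503.

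Interferon response genes were higher in LASS2-/- on both diets, with a list median of 0.32 log2 on chow and 0.96 on high-fat diet. Of 22 measured members, 5 rose and 0 fell over all genes, and 13 rose and 0 fell adjusted over the list alone. Ifi27 rose by 1.14 ± 0.10 (adjusted p = 0.000245), Oas1a by 1.12 ± 0.17 (adjusted p = 0.00668), Gbp3 by 0.96 ± 0.18 (adjusted p = 0.0195) and Igtp by 0.77 ± 0.11 (adjusted p = 0.00397). Of 23 macrophage and Kupffer cell markers, with medians of 0.24 and 0.66, 3 rose and 1 fell over all genes, and 16 rose and 1 fell adjusted over the list alone. Marco, Mpeg1, a macrophage perforin-like gene (0.83 ± 0.11, adjusted p = 0.00267), and Lyz2, lysozyme (0.64 ± 0.13, adjusted p = 0.037), rose, and Cd163, a scavenger receptor of resident macrophages, fell by 0.79 ± 0.16 (adjusted p = 0.0328). Both medians lay at or above the 99.99 percentile of random lists on both diets. Of the passing members named here, only Marco and Ifi27 also passed with every alternative other than the fit without trend.

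Beside these, of 18 endothelial markers 0 passed limma on either count and 1 had an unadjusted p under 0.05, with medians of 0.01 and 0.06, and the chow median was -0.09 with equal medians. Of 16 lymphocyte and plasma cell markers 0 passed over all genes, and 4 rose and 1 fell adjusted over the list alone, with medians of 0.34 and 0.10. The plasma cell genes Ighm and Jchain had high-fat genotype ratios of -1.54 and -1.30. Medians on chow and high-fat diet were 0.20 and 0.01 for 7 neutrophil markers, 0.10 and 0.20 for 8 cholangiocyte markers, and 0.11 and -0.30 for 5 erythroid markers. They were 0.10 and 0.00 for 5 pancreatic acinar markers, 0.04 and -0.02 for 8 adipocyte markers, and 0.10 and -0.26 for 5 skeletal muscle markers. In these lists 0 members passed limma over all genes, with unadjusted p under 0.05 in 3 neutrophil, 1 cholangiocyte, 3 erythroid, 2 acinar, 2 adipocyte and 1 muscle marker. Adjusted over the list alone, 2 neutrophil markers and 1 erythroid marker rose and 1 acinar, 1 adipocyte and 1 muscle marker fell. The cholangiocyte, acinar and muscle chow medians equal the difference of the chow floors, and the adipocyte chow median was -0.06 with equal medians.

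Another 4 lists lay above random lists on both diets. Of 23 collagen and fibrosis genes, with medians of 0.27 and 0.24, 1 rose and 0 fell over all genes and 5 rose adjusted over the list alone. The 1 gene was Col5a2, a fibrillar collagen, at 1.28 ± 0.26 (adjusted p = 0.0338). Of 20 fetal and tumour associated liver genes, with medians of 0.21 and 0.70, 2 rose over all genes, Tff3 and the galectin Lgals3 (0.75 ± 0.14, adjusted p = 0.0265), and 8 rose adjusted over the list alone. Of 22 genes of the unfolded protein and integrated stress response, with medians of 0.32 and 0.13, 2 rose over all genes, Creld2 (0.77 ± 0.12, adjusted p = 0.0049) and Sdf2l1 (0.56 ± 0.12, adjusted p = 0.0474), and 7 rose adjusted over the list alone. Of 12 metallothionein and heat shock genes, with medians of 0.19 and 0.17, 1 rose over all genes, the cochaperone Dnajb1 (1.03 ± 0.21, adjusted p = 0.0338), and 6 rose adjusted over the list alone. With arrays scaled to equal medians, chow medians were 0.13 for macrophage markers, 0.21 for interferon genes, 0.17 for collagens, 0.11 for fetal genes, 0.22 for the unfolded protein response and 0.09 for heat shock genes. Of the passing members of these 4 lists, Col5a2, Lgals3, Creld2, Sdf2l1 and Dnajb1 did not pass with quantile normalization or with equal medians, and Tff3 and Dnajb1 did not pass with robust moderation. Lists of 20 unchanged genes lay beyond either limit in 10% of simulations on the chow ratio. The simulated genes varied independently, so this is not the rate for lists whose genes move together.

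**Figure D3:**
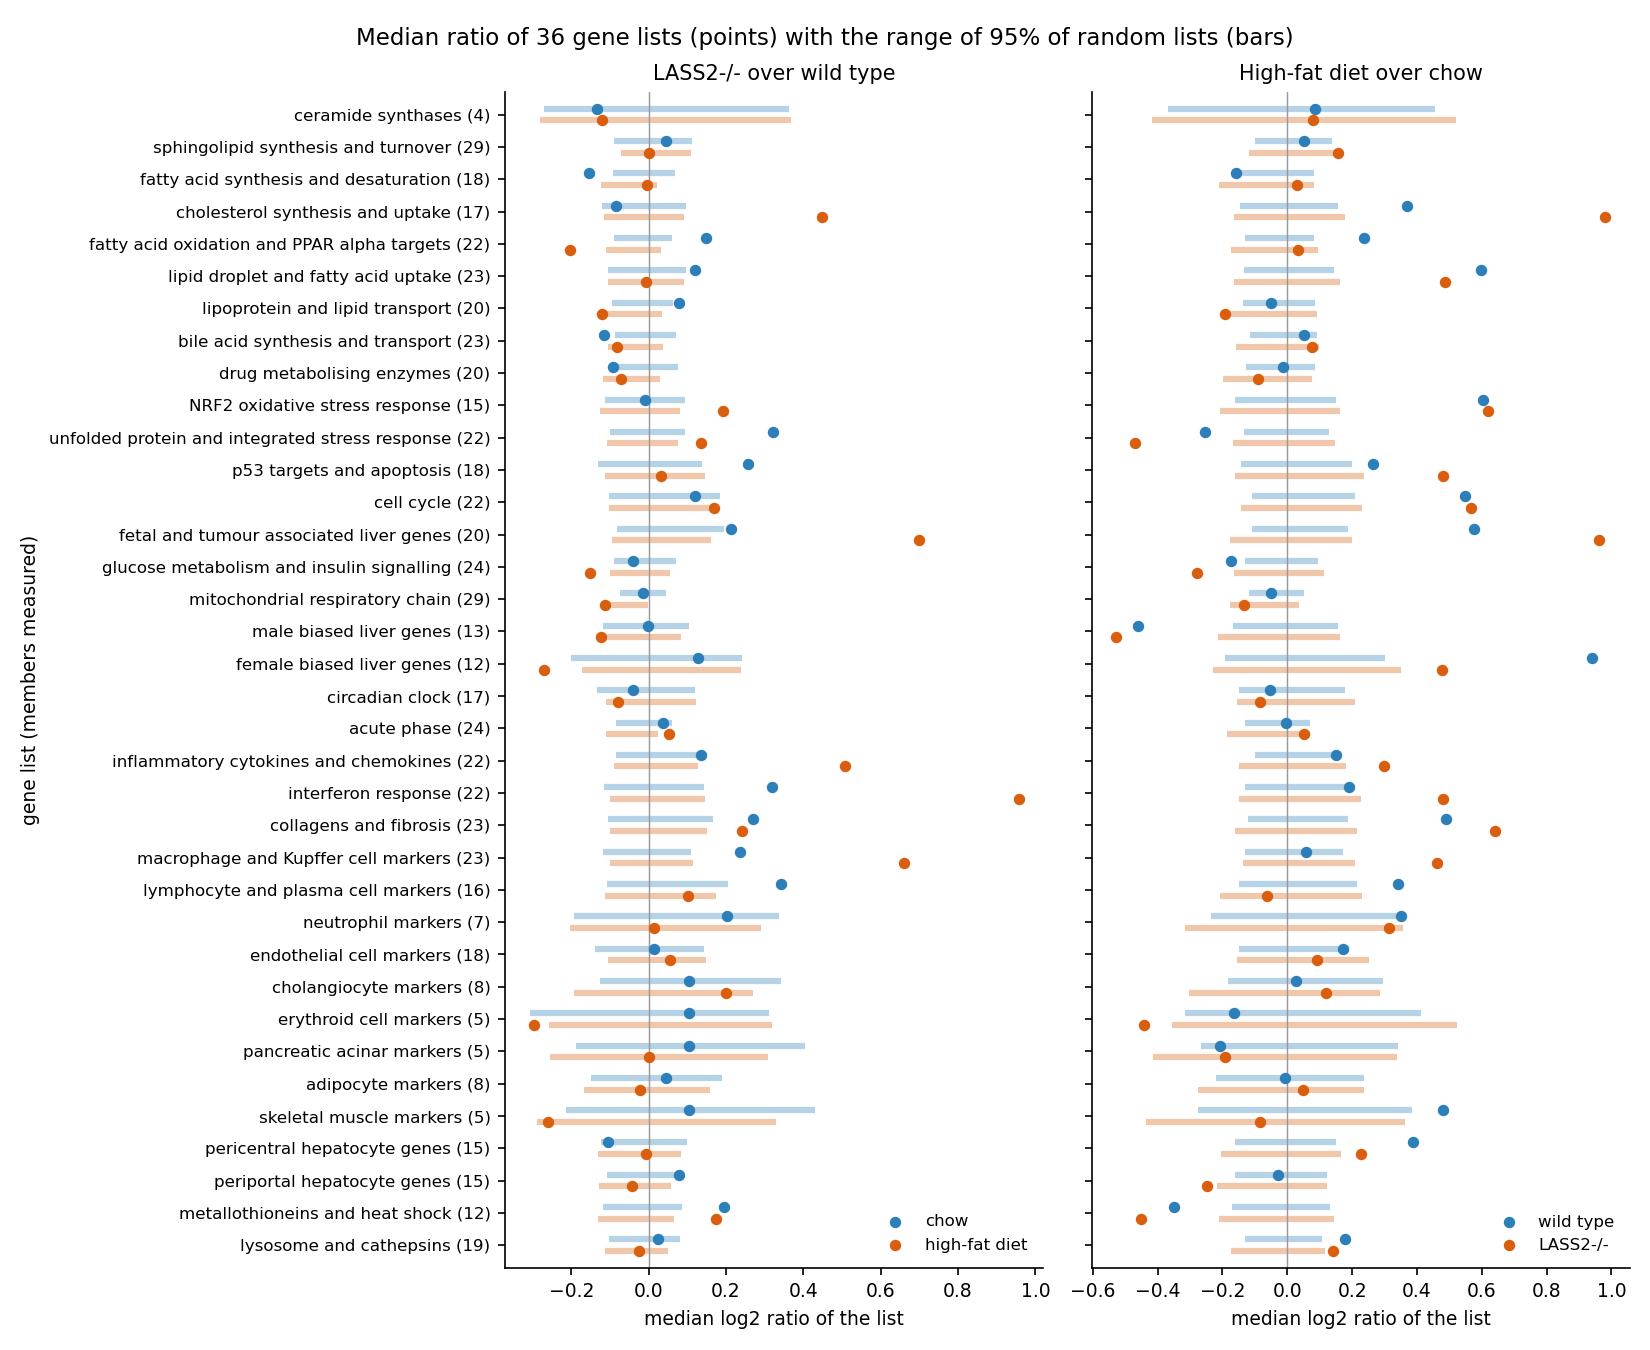
Median log2 ratio of 36 gene lists (points, horizontal axis) for LASS2-/- over wild type on each diet and for high-fat diet over chow in each genotype and the range of 95% of random lists as bars. Interferon genes reached 0.96 on high-fat diet for genotype, and cholesterol synthesis genes reached 0.98 in LASS2-/- for diet.

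Cidea and Cidec, which promote the fusion of lipid droplets, were among the genes raised most by the high-fat diet. Cidea was at least 30.8-fold higher in wild type and 46.2-fold higher in LASS2-/-, and Cidec was 12.1-fold and 8.90-fold higher. Lcn2, an iron-siderophore binding protein of the acute phase, was 6.50-fold and 34.0-fold higher, Ly6d 6.72-fold and 30.2-fold, and Cyp2b9, a cytochrome P450 more abundant in female liver, 14.4-fold and 7.53-fold. Hsd3b5, a steroid-metabolising enzyme of male liver, was 58.6-fold lower in wild type and 20.8-fold lower in LASS2-/-, and Lepr, the leptin receptor, was 10.3-fold and 18.7-fold lower. Fabp5, a fatty acid binding protein, was 10.1-fold and 5.72-fold lower, and Onecut1, a transcription factor of hepatocytes, 7.43-fold and 4.30-fold.

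These genes came from 116 genes at least 2-fold higher and 72 at least 2-fold lower in both genotypes, where independent lists would share 8.28 and 2.93. Another 5 were 2-fold apart in opposite directions, where 9.85 would be. The remaining named higher genes were Slc22a29 (11.1-fold and 7.74-fold), Slc22a27 (7.42-fold and 4.57-fold), Themis (6.35-fold and 10.5-fold), Mogat1 (4.99-fold and at least 6.10-fold), Ubd (at least 4.76-fold and 19.5-fold), Tpm2 (4.45-fold and 4.15-fold) and Ppp1r3c (5.07-fold and 4.13-fold). The remaining named lower genes were Abhd1 (5.81-fold and at least 6.09-fold), Ugt2b38 (5.61-fold and 5.37-fold), Slc25a30 (8.74-fold and 5.03-fold), Tff3 (at least 4.56-fold and 4.66-fold), Mpp4 (4.44-fold and 5.32-fold), Leng9 (at least 4.39-fold and at least 7.69-fold), Cdc42ep5 (4.63-fold and 4.33-fold) and Gadd45g (4.74-fold and 4.17-fold). In Themis only 1 of 2 probe sets and in Leng9 only 2 of 3 had a mean diet ratio over the genotypes in the stated direction. With the mean of all probe sets the mean log2 diet ratio was 1.51 for Themis, 1.62 for Tpm2, -0.78 for Leng9 and -1.46 for Cdc42ep5. All 24 passed limma for the mean diet effect, Cidea with adjusted p = 1.7e-09, Cidec at 3.38 ± 0.20 (adjusted p = 1.49e-07), Cyp2b9 at 3.38 ± 0.19 (adjusted p = 9.05e-08) and Hsd3b5 at -5.13 ± 0.24 (adjusted p = 3e-08). Because these genes were chosen on the same ratios that the test uses, passing is no separate support. With robust moderation Lcn2, Ly6d, Ubd and Hsd3b5 did not pass, nor did Leng9 with the mean of all probe sets. In total 782 genes rose and 630 fell, which is 1412 of 12493 genes. List counts for diet are to be read against this share. Without trend 0 passed, where 1783 genes had an unadjusted p under 0.05 against 2971 with it. By genotype, 266 genes were 2-fold higher and 155 lower in wild type and 389 higher and 236 lower in LASS2-/-, which became 495 and 189 in LASS2-/- with arrays scaled to equal medians, where the median ratio of all genes moved from -0.01 to 0.08. With the floor at the 25th percentile, which admitted 16898 genes, they were 961 higher and 1319 lower in LASS2-/-. There the excess of higher genes in LASS2-/- did not hold, but the floor and the genes entering changed together.

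**Figure D4:**
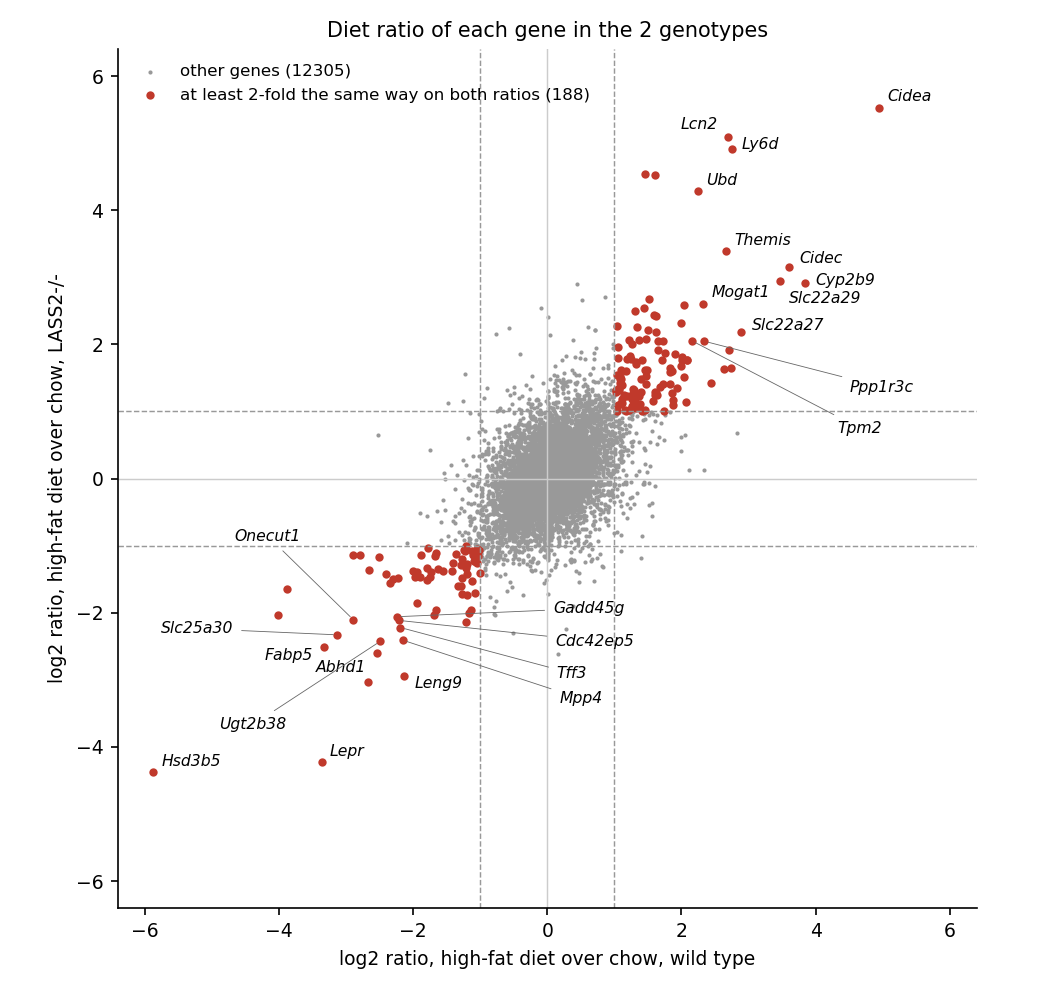
Log2 ratio of high-fat diet over chow in wild type (horizontal axis) and in LASS2-/- (vertical axis) for 12493 genes, 1 point per gene, with values floored at the array median and dashed lines at 2-fold. The 116 higher and 72 lower genes that were 2-fold apart in both genotypes are in red, with Cidea and Hsd3b5 at the extremes.

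On the high-fat diet, of 23 lipid droplet and fatty acid uptake genes, with medians of 0.60 in wild type and 0.49 in LASS2-/-, 12 rose and 1 fell over all genes, and 13 rose and 4 fell adjusted over the list alone. Beside Cidea, Cidec and Mogat1, these were led by Plin4, a lipid droplet coat protein, at 2.19 ± 0.20 (adjusted p = 7.68e-06). Of 17 genes of cholesterol synthesis and uptake, with medians of 0.37 and 0.98, 8 rose and 0 fell over all genes and 10 rose and 0 fell adjusted over the list alone. Hmgcs1, which makes the substrate of HMG-CoA reductase, rose by 2.02 ± 0.14 (adjusted p = 5.89e-07), Dhcr7 by 1.46 ± 0.24 (adjusted p = 0.000963), Idi1 by 1.22 ± 0.09 (adjusted p = 1.06e-06) and Sqle by 1.10 ± 0.17 (adjusted p = 0.000825). Of 15 genes of the NRF2 oxidative stress response, with medians of 0.60 and 0.62, 9 rose and 0 fell over all genes, and 12 rose and 1 fell adjusted over the list alone, led by the carbonyl reductase Cbr3 at 3.07 ± 0.43 (adjusted p = 0.000322) and the glutathione transferase Gstm3 at 1.72 ± 0.13 (adjusted p = 1.51e-06). Of 19 lysosome and cathepsin genes, with medians of 0.18 and 0.14, 4 rose and 0 fell over all genes and 5 rose adjusted over the list alone, among them Hexa at 0.47 ± 0.10 and Lipa at 0.47 ± 0.10. With robust moderation Hmgcs1, Dhcr7, Sqle and Cbr3 did not pass, all of which passed with the other alternatives that kept the trend.

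Of 22 cell cycle genes, with medians of 0.55 and 0.57, 8 rose and 0 fell over all genes and 11 rose and 1 fell adjusted over the list alone, among them the replication helicase gene Mcm2 at 1.89 ± 0.18 (adjusted p = 9.69e-06). Of 23 collagen and fibrosis genes, with medians of 0.49 and 0.64, 10 rose and 1 fell over all genes and 17 rose and 1 fell adjusted over the list alone. Col3a1, a fibrillar collagen, rose by 1.44 ± 0.12 (adjusted p = 3.71e-06), and Des, desmin of stellate and muscle cells, fell to below the floor on both high-fat arrays. Of 20 fetal and tumour associated liver genes, with medians of 0.58 and 0.96, 9 rose and 1 fell over all genes and 10 rose and 1 fell adjusted over the list alone, with Lcn2 at 3.89 ± 0.35 (adjusted p = 5.37e-06), Ly6d at 3.83 ± 0.35 (adjusted p = 6.49e-06) and Anxa2 at 1.86 ± 0.16 (adjusted p = 3.08e-06) higher and Tff3 lower. Of 18 p53 targets and apoptosis genes, with medians of 0.26 and 0.48, 5 rose and 1 fell over all genes and 6 rose and 3 fell adjusted over the list alone, led by the cell cycle inhibitor Cdkn1a at 1.70 ± 0.16 (adjusted p = 7.16e-06). Of 15 pericentral hepatocyte genes, with medians of 0.39 and 0.23, 5 rose and 0 fell over all genes and 7 rose adjusted over the list alone, led by Ahr, the aryl hydrocarbon receptor, at 1.73 ± 0.11 (adjusted p = 2.65e-07).

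Of 12 measured female-biased genes, with medians of 0.94 and 0.48, 5 rose and 0 fell over all genes and 7 rose and 1 fell adjusted over the list alone, among them Cyp2b9 and Abcd2 at 1.93 ± 0.21 (adjusted p = 3.49e-05). Of 13 male-biased genes, with medians of -0.46 and -0.53, 2 rose and 8 fell over all genes and 2 rose and 9 fell adjusted over the list alone, among them Hsd3b5, Ugt2b38 at -2.46 ± 0.19 (adjusted p = 1.4e-06) and Slco1a1 at -1.15 ± 0.09 (adjusted p = 1.51e-06). Hao2, which both sex lists hold, rose (adjusted p = 0.000372).

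Of 22 genes of the unfolded protein and integrated stress response, with medians of -0.25 and -0.47, 0 rose and 8 fell over all genes and 1 rose and 12 fell adjusted over the list alone, led by Creld2 at -1.50 ± 0.12 (adjusted p = 1.51e-06), Sdf2l1 at -1.31 ± 0.12 (adjusted p = 7.16e-06) and Dnajb9 at -0.85 ± 0.09 (adjusted p = 1.81e-05). Of 12 metallothionein and heat shock genes, with medians of -0.35 and -0.45, 9 fell and 2 rose on either count. Those that fell included Dnajb1 at -1.05 ± 0.21 (adjusted p = 0.00455) and Hsph1 at -0.95 ± 0.10 (adjusted p = 3.67e-05), and those that rose were the metal-binding genes Mt1 at 0.95 ± 0.10 (adjusted p = 1.66e-05) and Mt2. Of 24 genes of glucose metabolism and insulin signalling, with medians of -0.17 and -0.28, 9 fell and 2 rose over all genes and 13 fell and 2 rose adjusted over the list alone. Socs3, an inhibitor of cytokine signalling, fell by 1.90 ± 0.17 (adjusted p = 5.25e-06), Trib1 by 1.29 ± 0.24 (adjusted p = 0.00273) and Irs2, an insulin receptor substrate, by 1.17 ± 0.24 (adjusted p = 0.0056), and Ppp1r3c rose by 2.19 ± 0.11 (adjusted p = 3.74e-08). Dnajb1 did not pass with robust moderation, nor did Trib1 with the mean of all probe sets.

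Cell type markers had the following diet ratios, where 1412 of all 12493 genes passed limma. Macrophage markers had medians of 0.06 in wild type and 0.46 in LASS2-/-, where 4 of 23 rose and 1 fell, Cd163, and 5 rose and 1 fell adjusted over the list alone. Medians were 0.17 and 0.09 for 18 endothelial markers, of which Cdh5 rose (0.75 ± 0.17, adjusted p = 0.0125), and 0.34 and -0.06 for 16 lymphocyte markers, of which 3 rose and 4 rose adjusted over the list alone, with 0.02 in LASS2-/- under equal medians. They were 0.35 and 0.31 for 7 neutrophil markers, where Lcn2 rose, 0.03 and 0.12 for 8 cholangiocyte markers, where Cd24a rose, and -0.16 and -0.44 for 5 erythroid markers, where Car2 rose and Car1 fell. They were -0.21 and -0.19 for 5 acinar markers, of which 0 passed and 0 had an unadjusted p under 0.05, and 0.48 and -0.08 for 5 muscle markers, where Tpm2 rose. In the endothelial, neutrophil, cholangiocyte, erythroid, acinar and muscle lists the counts adjusted over the list alone equalled those over all genes. They were -0.01 and 0.05 for 8 adipocyte markers, where Cidec and Fabp4 rose and Slc2a4 fell, with 2 rising and 2 falling adjusted over the list alone, and the wild type median was 0.03 with quantile normalization. Cd163 did not pass with equal medians, nor Slc2a4 with no filter. Among lists named above, leaving out _x_at and _s_at probe sets took the wild type cell cycle median to 0.25, and averaging probe sets took the LASS2-/- medians of the lipid droplet, p53 and female-biased lists to 0.31, 0.26 and 0.31.

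The largest differences of the genotype ratio between the diets are given here as values. Limma called 0 genes for this difference in a fit that takes the mean genotype effect as its error, with 277 genes at an unadjusted p under 0.05. Cbr3, a carbonyl reductase, had a log2 genotype ratio of 0.76 on chow and 3.68 on high-fat diet, a difference of 2.91, and Gpx2, a glutathione peroxidase, went from at most -0.68 to 2.23. Cyp2c39 went from -0.28 to 2.89, Oasl1, an interferon-induced gene, from -0.54 to 2.29, Gipc2 from at most -0.01 to at least 2.64, and Ctse, cathepsin E, from at least 0.33 to 3.41, with 1 of its 2 probe sets going this way and a difference of 1.04 with the mean of both. Of the immediate early genes Egr1 and Btg2, Egr1 went from 2.89 on chow to 0.11 on high-fat diet, and Btg2 lay at -0.03 on high-fat diet with a difference of -2.53. Rap1gap went from 1.64 to -0.63 and Ciart, a clock repressor, from 0.79 to -1.42. Gpx2, Gipc2 and Ctse lay under the floor on at least 1 array.

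By list, the median over genes of the high-fat minus chow genotype ratio lay outside the range of 95% of random lists for 15 lists. It was 0.47 for interferon genes, 0.46 for cholesterol synthesis, 0.43 for macrophage markers, 0.37 for chemokines, 0.32 for the NRF2 list, 0.31 for fetal genes, 0.16 for fatty acid synthesis and 0.13 for acute phase genes. It was -0.55 for female-biased genes, -0.39 for erythroid markers, -0.28 for fatty acid oxidation, -0.20 for the unfolded protein response, -0.15 for periportal genes, -0.14 for heat shock genes and -0.12 for lipoprotein genes. In the NRF2 list the members with large differences were Cbr3, Abcc4 at 2.45 and Srxn1 at 1.24. With the mean of all probe sets the NRF2 difference was 0.13. These list differences were not tested.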

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

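The tests in this part were chosen after the result was seen, except the recomputations of the macrophage, interferon and NRF2 medians with quantile normalization. The values of single genes and of the lipoprotein list under other settings also came from the alternatives set beforehand.

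The signal of Cers2 was about equal on all 4 arrays although 2 of them were labelled LASS2-/-. With a range over the 4 arrays of 0.214 log2 the signal does not separate the genotypes, so it does not decide whether labels were exchanged within a diet, which stays open. The probe set may read a part of the transcript that the knockout leaves, with a mean genotype ratio of -0.041, but which part it reads was not determined, so this stays open. That both arrays labelled LASS2-/- came from mice with an intact gene also stays open: other genes differed between the labels on both diets, Marco by 3.67-fold and 8.44-fold, and the labelled split called 114 genes against 0 for the exchanged split, but 2 splits are too few to decide and none of these values reads the targeted locus.

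Macrophage and interferon genes were higher on both LASS2-/- arrays. A different intensity distribution of the arrays would lose the pattern under quantile normalization, and the lowest of the 4 medians was then 0.236. A lower share of hepatocytes would raise endothelial markers alike, but the macrophage median exceeded the endothelial median by 0.22 on chow (95% interval from resampled genes 0.101 to 0.34) and by 0.60 on high-fat diet (0.34 to 0.94), and the macrophage and endothelial lists share 0 genes. Against cholangiocyte markers the interval on high-fat diet ran from -0.02 to 0.88 and held 0. On chow the lymphocyte and neutrophil medians given above lay near the macrophage median, while on high-fat diet they lay well below it. The intervals carry no error between arrays or animals, so a lower share of hepatocytes is not excluded. An effect of the genotype or of single animals remains open with 1 array per group, and more or activated macrophages may be part of it, since 20 of 23 markers were higher on chow (54.6% of all genes; 19 markers with equal medians) and 22 on high-fat diet (54.3% of all genes), but Cd163, a marker of resident macrophages, fell by 0.79 (adjusted p = 0.0328).

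The NRF2 list had a higher genotype ratio on high-fat diet than on chow, by a median of 0.32. A different intensity distribution would end this under quantile normalization, where it was 0.422. With the mean of all probe sets it was 0.135, so its size depended on the choice of probe set. The list medians of the diet ratio given above were nearly equal in wild type and LASS2-/-, unlike the median of the differences gene by gene. Of 15 members, 10 had their highest signal on the LASS2-/- high-fat array, so a property of that 1 array or animal could give the whole pattern. This cannot be told apart from an effect of genotype and diet together, because the group has no other array.

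Several genes and lists went in opposite directions in different groups. For the genotype ratio on high-fat diet minus that on chow, the differences were at least 2.61 for Arhgef25, 2.78 for Tatdn1, at most -2.59 for Arhgef40, -2.30 for Cyp26b1, at most -2.19 for Sct and at most -2.16 for Hand1, each 2-fold apart one way on chow and the other way on high-fat diet. Gm9112 had a difference of at least 2.42 and was 2-fold apart in opposite directions with the diet, at most -1.26 in wild type and 1.16 in LASS2-/-. In Tatdn1 2 of 4 probe sets and in Arhgef25 1 of 3 had a difference of the stated sign. With the mean of all probe sets the differences were 0.39 for Tatdn1, 0.74 for Arhgef25 and -1.19 for Arhgef40, and that of Arhgef40 was -0.90 without _x_at and _s_at probe sets, so none of these 3 was then 2-fold apart in opposite directions. The genes Arhgef25, Arhgef40, Sct, Hand1 and Gm9112 lay under the floor on at least 1 array. The median genotype ratio of fatty acid oxidation genes was higher than random lists on chow and lower on high-fat diet, a difference of -0.35, and that of lipoprotein and lipid transport genes likewise, a difference of -0.20. The lipoprotein chow median of 0.08 was -0.03 with arrays scaled to equal medians. The differences of the lists were not tested. For the single genes, limma with the mean genotype effect as error called 0 genes for the difference between diets, with 277 at an unadjusted p under 0.05. Among 3954 probe sets without a single gene name, 5 were 2-fold apart in the same direction on both diets for genotype, where 0.896 would be if the ratios were independent, and 52 in both genotypes for diet, where 2.96 would be.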

How the results depend on the processing

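The robust moderation and the tolerance applied to correlations were chosen after the result was seen. Of the counts and correlations under alternatives, 67 stayed within 1.5-fold or within the tolerance and 43 moved, not including counts of genes 2-fold apart in opposite directions, of which 6 stayed and 6 moved. For medians of the lists beyond random lists on both ratios, 155 moved by less than the spread between the independent ratios and 45 by more, and for named genes 236 and 31 (for differences between diets, against the spread of genes of like signal), with 0 changes of sign. Of 104 medians of the other lists, 26 changed sign under at least 1 alternative. Looser rules admit more genes by construction. With the 1.5-fold threshold the counts higher and lower were 710 and 419 for genotype on chow, 716 and 415 for genotype on high-fat diet, 963 and 638 for diet in wild type and 1267 and 900 for diet in LASS2-/-, with 122 and 42 shared for genotype and 428 and 273 for diet, and 79 and 58 in opposite directions. With the floor at the 25th percentile 16898 genes entered, so the floor and the genes changed together. The counts in the same order were 1156 and 633, 790 and 786, 1008 and 850, and 961 and 1319. In this setting the excess of higher genes for genotype on high-fat diet ended, and that for diet in LASS2-/- turned to lower. Shared counts were 131 and 67 for genotype and 247 and 197 for diet, with 205 and 189 in opposite directions. The correlations across genes were 0.036 for genotype and 0.25 for diet. With arrays scaled to equal medians 95 genes were lower on chow, 9 were shared higher, limma gave 11 and 11 for genotype and 358 lower for diet. With quantile normalization 4 were shared lower and limma gave 14 and 9 for genotype. With the mean of all probe sets 3 and 1 were in opposite directions. Limma gave 33 and 19 for genotype with no filter, 36 and 27 with the mean of all probe sets and 41 higher with robust moderation. Without trend limma gave 0 and 0 for genotype and 0 and 0 for diet, with 820 and 1783 genes at an unadjusted p under 0.05. For scaling, filter, probe set and moderation settings the cause was not tested. Of the main calls for genotype, limma shared 23 with quantile normalization, 22 with equal medians, 52 with no filter, 55 with the mean of probe sets and 79 with robust moderation. No paired analysis was possible because the labels carry no numbers that pair the arrays. Ratios with an array under the floor are only bounds.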

Other observations

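The tests of exchanged arrays and of neighbouring genes given in this part were chosen after the result was seen. Several lists not described above held members that passed limma for genotype. Of 18 fatty acid synthesis genes, 0 rose and 2 fell, Srebf1 and Acaca, neither of which passed with quantile normalization, and 1 rose and 4 fell adjusted over the list alone, with medians of -0.16 on chow and 0.00 on high-fat diet, the latter 0.03 with quantile normalization. Of 20 drug metabolising enzymes, 1 rose, Gstm3 (1.05 ± 0.13, adjusted p = 0.0026), and 3 fell, Cyp2c37, Cyp2c29 and the carboxylesterase Ces2a (-0.61 ± 0.10, adjusted p = 0.00668), against 2 and 5 adjusted over the list alone. Gstm3 did not pass with equal medians or robust moderation, Ces2a with quantile normalization or Cyp2c29 with no filter. Of 23 bile acid genes, the transporters Slco1a4 and Abcc3 fell, and 1 rose and 3 fell adjusted over the list alone, but neither passed with quantile normalization. Of 22 chemokine and cytokine genes, with medians of 0.13 and 0.51, Ccl5 and Cxcl9 (1.11 ± 0.14, adjusted p = 0.0026) rose, and 5 rose adjusted over the list alone. Of 24 acute phase genes, Saa2 rose and Hamp2, a hepcidin gene, fell (-0.65 log2), and 5 rose and 1 fell adjusted over the list alone, but Saa2 did not pass with quantile normalization. Of 17 cholesterol synthesis genes, with medians of -0.08 and 0.45, Idi1 rose, and 4 rose adjusted over the list alone, but Idi1 did not pass with quantile normalization or equal medians. Of 29 respiratory chain genes 0 passed limma for genotype or for diet on either count, while 2 and 4 had an unadjusted p under 0.05.

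With the high-fat diet, bile acid genes moved in both directions, with 8 of 23 rising and 4 falling over all genes and adjusted over the list alone. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 1.39 ± 0.11 (adjusted p = 2.03e-06) and the sterol hydroxylase Cyp8b1 by 1.74 ± 0.10 (adjusted p = 9.13e-08), while Cyp2c70 fell by 1.41 ± 0.11 (adjusted p = 1.2e-06). Of 24 acute phase genes 9 rose and 5 fell, against 9 and 7 adjusted over the list alone, with Saa2 at 2.01 ± 0.15 (adjusted p = 1.4e-06) and Orm2 at 1.80 ± 0.18 (adjusted p = 1.25e-05). Of 18 fatty acid synthesis genes 3 rose and 4 fell, against 3 and 5 adjusted over the list alone, with Gpam at 0.92 ± 0.09 (adjusted p = 7.66e-06) and the elongase Elovl6 at -1.16 ± 0.09 (adjusted p = 1.27e-06). Of 22 fatty acid oxidation genes 4 rose and 3 fell, against 9 and 4 adjusted over the list alone, with Vnn1 at 1.36 ± 0.10 (adjusted p = 1.33e-06) and Pdk4 at -1.55 ± 0.17 (adjusted p = 3.49e-05). Of 22 interferon genes 3 rose, Ifit1, Usp18 and Rsad2, and 5 rose adjusted over the list alone, with medians of 0.19 and 0.48. Of 29 sphingolipid genes, Sgms1 and Asah1, acid ceramidase, rose and Ugcg, glucosylceramide synthase, fell by 0.83 ± 0.18 (adjusted p = 0.00718), the same counts as adjusted over the list alone. This is no larger a share than the 1412 of all 12493 genes that passed for diet. Sgms1 and Asah1 did not pass with quantile normalization or equal medians, Ugcg with the mean of all probe sets, or Rsad2 with robust moderation. Of 15 periportal hepatocyte genes 0 rose and 6 fell, against 1 and 7 adjusted over the list alone, among them Hal at -0.55 ± 0.10 (adjusted p = 0.0024). Of 17 circadian clock genes 3 rose and 3 fell on either count. Those passing limma were Nfil3 (adjusted p = 7.8e-05), Dbp (0.00202), Hlf (0.00312), Cry1, Ciart and Arntl. Cry1 did not pass with equal medians, nor Ciart and Arntl with quantile normalization. Dbp also fell with the LASS2-/- label, but not with quantile normalization. Whether clock phase or feeding differed between the single arrays was not tested.

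Exchanging the genotype labels within 1 diet gives 2 splits of the arrays, and the exchanged split is the difference of the genotype effect between diets. The real split called 114 genes with limma and was the only 1 of the 2 with as many, and the other called 0, with 277 genes at an unadjusted p under 0.05. These splits are too few for a share under 0.05.

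A hypothesis was that variants of another strain next to the targeted gene account for the genotype calls. Of the 114 called genes, 2, Tuft1 and Lce1h, were among the 200 tested genes nearest to Cers2, which is 1.75% (exact 95% interval 0.213 to 6.19) and lay at the 59.1 percentile of random gene sets. The neighbours' median absolute mean genotype change of 0.197 lay at the 96.8 percentile, so some effect on the neighbours stays open. The length of such a region was not known and 200 genes were a chosen size, but the whole chromosome held 5 of the 114 (4.39%, exact 95% interval 1.44 to 9.94) and 5.01% of all tested genes with a known position. Most calls therefore lay on other chromosomes, while effects of linked variants on genes elsewhere and differences in strain background away from the locus stay open.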
